A study of Arabidopsis thaliana with 3 samples.

How the data were processed

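Small RNA was sequenced from inflorescences of Arabidopsis thaliana plants of 3 genotypes, per the labels: wild type (wt), the mutant apc8-1 of a subunit of the anaphase promoting complex, and a mutant of RNA polymerase IV (pol-iv). 1 library per genotype was analysed here, although the series' design text speaks of libraries in duplicate. Per the labels' protocols, total RNA was isolated with TRIzol from plants grown in soil in long days, and libraries were made with Illumina's protocol.

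The deposited files of the authors hold raw read counts, 1 count for each distinct sequence, with no normalization. Each listed sequence in the 3 files was 24 nt long. The sum of a file is therefore the 24-nt class alone and not the depth of the library, which is unknown here. Trimming, the aligner and any filter are not given in the sources used here, and the submitters' processing notes name the genome build TAIR10. Small RNA size classes could not be compared, because no other length was analysed here.

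Each sequence was placed on both strands of the reference assembly TAIR10.1 by exact match, with 0 mismatches allowed. A read with several places was counted once in sums over annotation classes, at the first class that any of its places touched, in the order rRNA, tRNA, miRNA gene, tasiRNA gene, snRNA or snoRNA, transposon-named gene, pseudogene, protein-coding gene, other non-coding gene, 1 kb upstream of a coding gene, and intergenic. The annotation has no transposable elements by superfamily. Only 149 genes whose record names a transposon formed that class, so reads of other transposons fall into the other classes. Windows, chromosomes and RdDM genes used reads with 1 place. Pericentromeres were the parts within 3 Mb of 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5.

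Loci were fixed windows of 500 bp, and the 12th base of a read set its window. A window was used if wt or apc8-1 had at least 20 reads. It was called Pol IV-dependent if pol-iv was at least 4-fold below wt, with pol-iv counts under 3 set to 3. Windows at least 2-fold lower or higher in apc8-1 were counted. That choice uses wt for both ratios, so windows with a chance high wt count lean low. For this reason, the same counts were made with windows chosen on wt plus apc8-1, with at least 40 reads and pol-iv at least 4-fold below their mean. Counts were also redrawn 100 times with 1 apc8-1 to wt ratio in every window, that of all uniquely placed nuclear reads. The windows were chosen anew in each redraw.

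The named loci were chosen by a rule set before the data were examined. In each comparison these were the 10 lowest and the 10 highest among windows with at least 100 reads in the pair of libraries, ranked by the bound of the ratio's interval nearer to 1, with adjacent chosen windows joined. The fixed lists were 31 miRNA families, 8 tasiRNA genes, 11 RdDM targets and 9 pathway genes, and a member was measured with at least 20 reads in the pair of libraries. Mature miRNAs are mostly shorter than 24 nt, so the families were measured by 24-nt reads on the sense strand of 100 annotated genes. RdDM genes were taken with 1000 bp upstream.

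No test was possible with 1 library per genotype, and no p-value is given. Counts have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95%. They cover counting error only, since no molecular identifiers are stated. Medians over windows have order-statistic intervals, and differences of such medians have bootstrap intervals over windows. Fold values against a count of 0 were computed against 3 counts, which is 1.22 parts in 1e6 of the listed reads in wt, 1.46 in apc8-1 and 32.6 in pol-iv.

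As the files hold part of a library, levels were compared as found. Other settings, fixed at the same time as that rule, scaled by the listed miRNA reads or by the median window ratio, left out reads on structural RNA and organelles, counted each distinct sequence once, and changed the window size, the minimum count and the thresholds. Scaling by the listed tasiRNA reads or by all 24-nt reads, sharing out reads with several places, distinct sequences in windows, windows chosen on the sum, and leaving out the 100 strongest windows, MIR163, TAS1C or the inverted repeat were added after seeing the data.

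The steps were tested on simulated data. All 2000 24-base sequences cut from chromosome 4 were found at their place. In simulated apc8-1 against wt counts over 10520 windows, the changed windows were drawn among those with at least 100 reads in the pair of libraries. All of the 100 windows lowered 4-fold and 93% of the 100 windows lowered 2.5-fold were called 2-fold lower. Of unchanged windows of any size, 2.60% and 2.69% were called lower, and of those with at least 100 reads 0.101% and 0.0757%. Recovery of changed windows with fewer reads was not tested. Intervals held the true ratio in 96.2% and 96.1% of the windows. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9 and blastn 2.17.0 were used.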

Results

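The data comprised 3 small RNA libraries of Arabidopsis inflorescences, 1 each from wt, apc8-1 and pol-iv plants. APC8 is a subunit of the anaphase promoting complex, a ubiquitin ligase, and Pol IV makes the precursors of most 24-nt siRNAs in RNA-directed DNA methylation (RdDM). The wt library held 2455136 reads of 24 nt in 789781 distinct sequences, apc8-1 held 2056914 reads in 654424 sequences, and pol-iv held 92045 reads in 19054 sequences. Exact places in the genome were found for all but 6.34% of the wt reads, 6.75% of the apc8-1 reads and 12.5% of the pol-iv reads. There was no replicate, so the values describe these libraries. Intervals are at 95%, and those of counts, ratios and shares cover counting error only. Intervals of medians and of their differences describe the spread over windows of the same libraries. Windows are not replicates, so these do not measure variation between libraries either.

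The comparison of pol-iv with wt shows which 24-nt reads depended on Pol IV. The 24-nt total of pol-iv was 0.0375 of wt (interval 0.0372 to 0.0377), a 26.7-fold difference. Without rRNA, tRNA, snRNA, snoRNA and organelle reads the difference was 45.8-fold. Uniquely placed reads were 165-fold lower in pericentromeres, the transposon-rich parts around the centromeres, and 42.8-fold lower in chromosome arms. NRPD1, which encodes the Pol IV catalytic subunit, had 2 reads in wt and 0 in pol-iv, too few to check the label.

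By annotation, reads within 1 kb upstream of coding genes were 404-fold lower in pol-iv (interval 381 to 429) and intergenic reads were 278-fold lower (268 to 287). Pseudogenes were 161-fold lower and protein-coding genes 35.9-fold lower. Transposon-named genes were 8.47-fold lower (8.02 to 8.95). Without an inverted repeat on chromosome 3, whose uniquely placed reads were at 0.609 of wt in pol-iv, they had 9772 reads in wt and 15 in pol-iv, a ratio of 0.00154. With each distinct sequence counted once, upstream reads were at 0.00569 of wt, pseudogenes at 0.00350 and protein-coding genes at 0.0473. Structural RNAs differed in direction as found: rRNA reads were 1.23 times wt, tRNA reads 1.18 times and snRNA or snoRNA reads 1.91 times. The depth is unknown, and the listed miRNA genes were at 1.47 of wt and the tasiRNA genes at 0.689. Relative to the miRNA genes, rRNA and tRNA reads would lie below wt, so their direction depends on the scaling. Organelle reads outside rRNA and tRNA genes were 0.751 of wt.

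**Figure D1:**
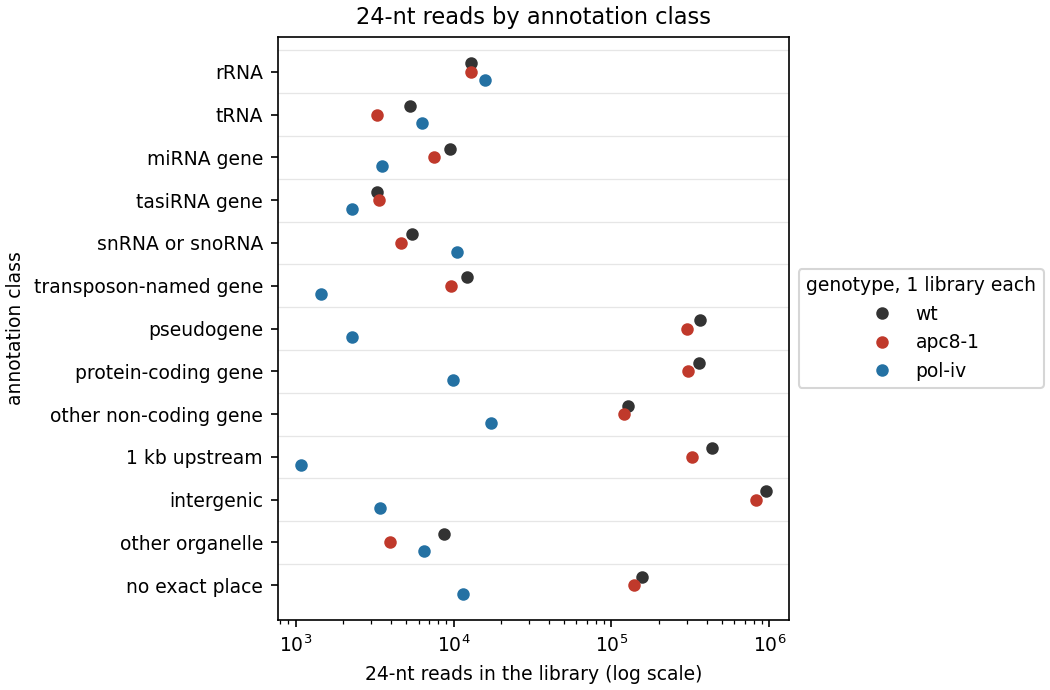
24-nt reads of each library (log scale) by annotation class, with 1 point per genotype. In pol-iv the intergenic, upstream and pseudogene classes fall to 3437, 1078 and 2266 reads, whereas rRNA, tRNA and snRNA or snoRNA reads stay at or above the wt points.

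Of 10674 windows of 500 bp, 10520 (98.6%) were at least 4-fold lower in pol-iv than in wt, and 9710 of these had no pol-iv read. Only 14 windows were at least 2-fold higher, all of them in chromosome arms. A window 1042 bp upstream of the pseudogene AT4G07031 on chromosome 4 (4105001 to 4105500) had 14809 reads in wt and 2 in pol-iv, a ratio of 0.000135 (1.64e-05 to 0.000488). A window in the non-coding gene AT4G05995 on chromosome 4 (7592501 to 7593000) had 12201 and 2 reads. The window 501 bp downstream of PYL10, an abscisic acid receptor gene, on chromosome 4 (13902501 to 13903000) had 13251 and 3 reads. A coding exon of AT4G08545 on chromosome 4 (5439001 to 5439500) had 12994 and 5 reads. In the non-coding gene AT3G05025 on chromosome 3 (9707001 to 9707500), wt had 5567 reads and pol-iv 0. This is 1856-fold lower against the floor of 3 counts, with a ratio interval up to 0.000663.

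The 10 loci with the highest pol-iv ratio lay mainly at genes of structural or other non-coding RNA. A cluster of snoRNA genes within AT5G15022 on chromosome 5 (4866501 to 4867000) had 1280 reads in wt and 5451 in pol-iv, 4.26 times (4.01 to 4.53). The snoRNA gene AT3G24615 on chromosome 3 (8979501 to 8980000) had 83 and 702 reads, and AT1G20015 on chromosome 1 (6941001 to 6941500) had 124 and 354. The non-coding gene AT4G26255 on chromosome 4 (13295501 to 13296500) had 81 and 502 reads, 6.20 times (4.89 to 7.94). The window of MIR165a on chromosome 1 (78501 to 79000) had 51 and 114 reads.

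The fixed miRNA and tasiRNA genes, whose products do not need Pol IV, served as background. Of 31 miRNA families, 13 were measured. Their median log2 ratio was 1.12 in pol-iv, with 12 above wt, MIR156 equal at 113 reads, and 8 at least 2-fold higher. Scaled by the listed miRNA reads, the median was 0.56, with 10 above, 3 below and 3 at least 2-fold higher. MIR163 had 1134 reads in wt and 1449 in pol-iv (1.28 times, 1.18 to 1.38), and MIR171 had 25 and 76, although as many distinct sequences in pol-iv as in wt (1.00). MIR163 fell below wt, at 0.869, when scaled by the listed miRNA reads. It supplied most of these itself, 1134 of 1555 in wt and 1449 of 2286 in pol-iv, and the rest were at 1.99 of wt. Of 8 tasiRNA genes, 6 were measured and 5 were lower in pol-iv. TAS1C, the most abundant, had 2332 and 1761 reads (ratio 0.755, 0.709 to 0.804), and TAS3 had 197 and 66 (0.335). TAS1C was 1.10 times wt when scaled by the listed tasiRNA reads, of which it supplied most itself, 2332 of 3297 in wt and 1761 of 2270 in pol-iv. In sum, the listed miRNA genes were at 1.47 of wt (1.38 to 1.57) and the tasiRNA genes at 0.689 (0.652 to 0.727).

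Among RdDM targets, SDC, FWA and QQS were measured in this comparison, and each had reads in wt and none in pol-iv. Folds here are against the floor of 3 counts, and the upper bound of the ratio's interval follows. SDC, an F-box gene with tandem repeats upstream (chromosome 2, 7682162 to 7684083), went from 101 reads to 0, 33.7-fold lower (ratio up to 0.0372). FWA, an imprinted homeobox gene (chromosome 4, 13038360 to 13042464), had 29 and 0 reads, 9.67-fold lower (up to 0.136). QQS, an orphan gene that regulates starch (chromosome 3, 12349047 to 12349933), had 37 and 0 reads, 12.3-fold lower (up to 0.105). The pathway genes DRD1, a chromatin remodeller gene with 42 wt reads, and DCL3, the gene of the Dicer that makes 24-nt siRNAs, with 40, also had no pol-iv read. The other 8 targets had fewer than 20 reads in the pair of libraries. SNC1, an immune receptor gene, had 16 reads in wt and 1 in pol-iv (ratio 0.0625, 0.00149 to 0.402).

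The comparison of apc8-1 with wt addresses whether the complex, which the study's title links to the RdDM protein DMS3, affects siRNA levels. The apc8-1 24-nt total was 0.838 of wt (0.836 to 0.839), a log2 ratio of -0.26. Among background genes, the listed tasiRNA genes were at 1.02 of wt (0.976 to 1.07), and at 1.00 without TAS1C, which had the most reads. The listed miRNA genes were at 1.23 (1.15 to 1.32), but at 0.753 (0.649 to 0.873) without MIR163, with 421 and 317 reads. The total was at 0.681 of wt when scaled by the listed miRNA reads and at 1.11 when scaled by these without MIR163. Uniquely placed reads were at 0.858 of wt in pericentromeres and 0.857 in arms. Of 219 bins of 500 kb with at least 1000 wt reads, 203 were below wt, with ratios from 0.426 to 1.10. The depth of the libraries is unknown, so the totals alone do not separate a change in siRNA from a difference in depth.

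**Figure D2:**
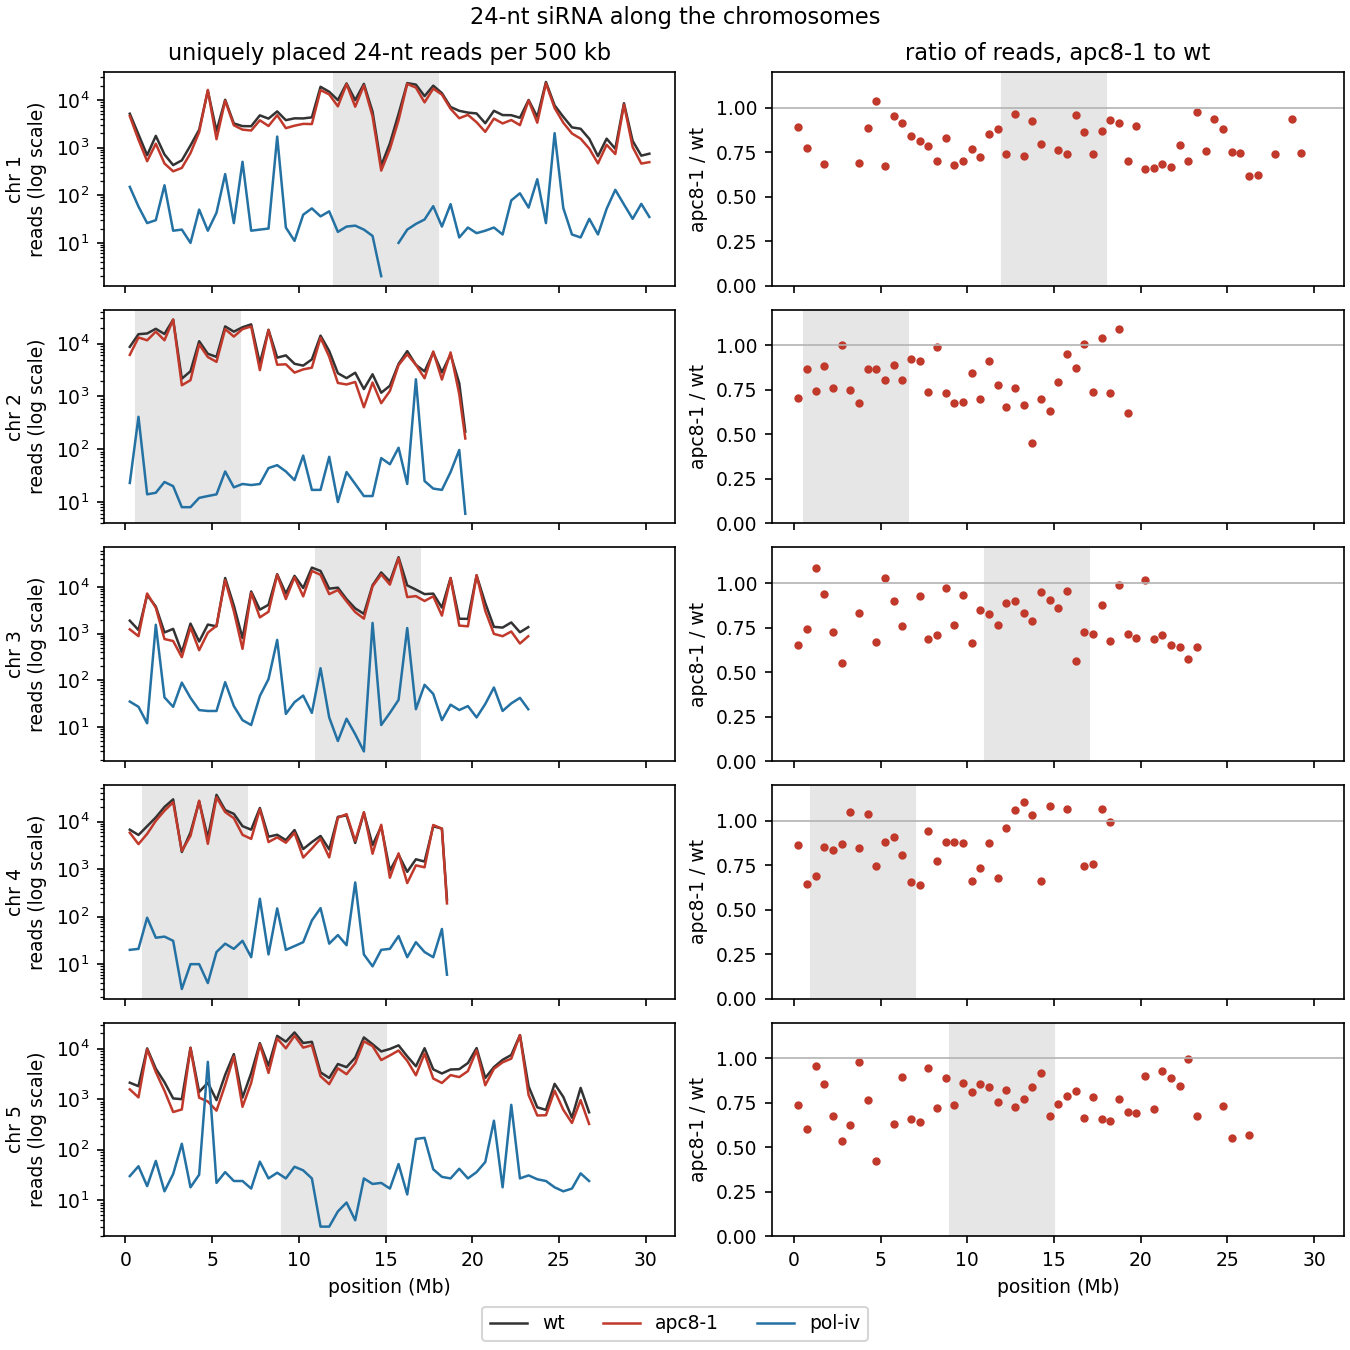
Uniquely placed 24-nt reads per 500 kb (left, log scale, gaps where a bin has 0 reads) and the apc8-1 to wt ratio in bins with at least 1000 wt reads (right) against position in Mb, with 1 line per library and pericentromeres in grey. The apc8-1 line follows wt slightly below it, with 203 of 219 bins under a ratio of 1, and pol-iv lies far below both except at a few isolated bins.

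By annotation, the apc8-1 ratio was 0.746 (0.742 to 0.749) within 1 kb upstream of coding genes, which was below that of the total. It was 0.819 in pseudogenes, 0.854 in protein-coding genes, 0.862 in intergenic regions (0.860 to 0.865) and 0.935 in other non-coding genes. Transposon-named genes were at 0.790, and at 0.974 (0.947 to 1.00) without the inverted repeat on chromosome 3. Reads of rRNA were at 0.991 (0.967 to 1.02), tRNA reads at 0.612 and organelle reads outside rRNA and tRNA genes at 0.458. When scaled by all 24-nt reads, intergenic regions were at 1.03 and protein-coding genes at 1.02 of wt, so their direction depended on the scaling, whereas the upstream class was at 0.890.

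Of the 10520 Pol IV-dependent windows, 2205 were at least 2-fold lower in apc8-1, 46 (0.437%) were at least 2-fold higher and 8269 lay within 2-fold. The median log2 ratio was -0.53 (-0.54 to -0.51), a ratio of 0.695. With 1 ratio in every window, redrawn counts gave 3.72% lower, 0.112% higher and a median of -0.24. That ratio was 0.858, the one of all uniquely placed nuclear reads, which lies above the median of the windows. No redraw was made at the median ratio, so the excess of lower windows over 3.72% includes this offset. Windows chosen on wt plus apc8-1 gave 1365 lower and 48 higher of 8857, with a median of -0.47. The other 154 windows, which did not meet the rule for Pol IV dependence, had 21 lower and 48 higher. The choice of windows alone gave 20.4% higher, and in sum these windows were at 0.883 of wt. The inverted repeat on chromosome 3 weighs on this sum, as 6 transposon-named windows within it had 2065 reads in wt and 66 in apc8-1. The 154 windows are not a set of Pol IV-independent loci. The floor of 3 pol-iv counts keeps windows with few wt reads in this group even without a pol-iv read. An example was 5 windows upstream of coding genes, with 24 reads in wt, 213 in apc8-1 and 0 in pol-iv. Scaling by the median window ratio left 603 lower and 356 higher windows, and scaling by all 24-nt reads 1189 and 132. The latter moved the median log2 ratio to -0.27, and scaling by the listed miRNA reads moved it to -0.82. MIR163 supplied 1597 of these 1914 miRNA reads in apc8-1, and this scaling was not run on windows without it. With each distinct sequence counted once, 526 of 6123 windows (8.59%) were lower and 13 higher, with a median of -0.30.

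Windows with many reads had higher apc8-1 to wt ratios than the others. A scaling of the libraries shifts all of them alike, so the difference between them does not depend on it, whereas which of them lies nearer to wt does. Among windows chosen on wt plus apc8-1, the median log2 ratio was -0.53 in the 4695 windows with 40 to 99 reads, -0.49 in 2688 with 100 to fewer than 300, and -0.25 (-0.28 to -0.21) in 1474 with 300 or more. In pericentromeres it went from -0.46 to -0.10, and in arms from -0.60 to -0.33. Redrawn counts had a median of -0.22 in each. The 100 windows with the most reads held 26.2% of the uniquely placed wt reads and were at 1.05 of wt in apc8-1 (1.04 to 1.05), and the rest at 0.790 (0.788 to 0.792).

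**Figure D3:**
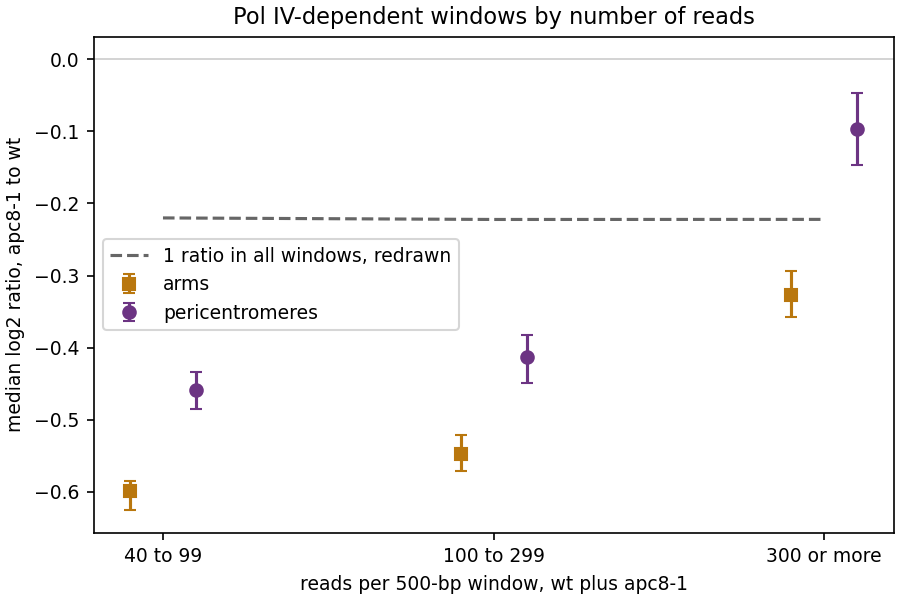
Median log2 ratio of apc8-1 to wt in Pol IV-dependent 500-bp windows, by the reads of wt plus apc8-1 in the window, in arms and pericentromeres. Bars are 95% order-statistic intervals of the median over windows and the dashed line is the median of counts redrawn at 1 ratio; windows with 300 or more reads have the highest medians, at -0.33 in arms and -0.10 in pericentromeres.

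The locus with the lowest apc8-1 ratio lay on chromosome 3 (16159001 to 16161000), over coding exons of AT3G44570 and AT3G44580, which the annotation names as transposon genes. It had 1936 reads in wt, 54 in apc8-1 (ratio 0.0279, 0.0209 to 0.0365) and 1209 in pol-iv. Both genes, on opposite strands, overlap an inverted repeat (16158264 to 16161642), examined after the values were seen, whose 3379 bp align to their own reverse complement at 90.5% identity. Over this repeat apc8-1 was 23.6-fold below wt (19.1 to 29.5) and pol-iv at 0.609 of wt. The 12 windows beside the repeat, in a segment of 10 kb from 16155001, were also lower in apc8-1, with 160 reads in wt, 47 in apc8-1 (0.294, 0.208 to 0.409) and 0 in pol-iv.

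**Figure D4:**
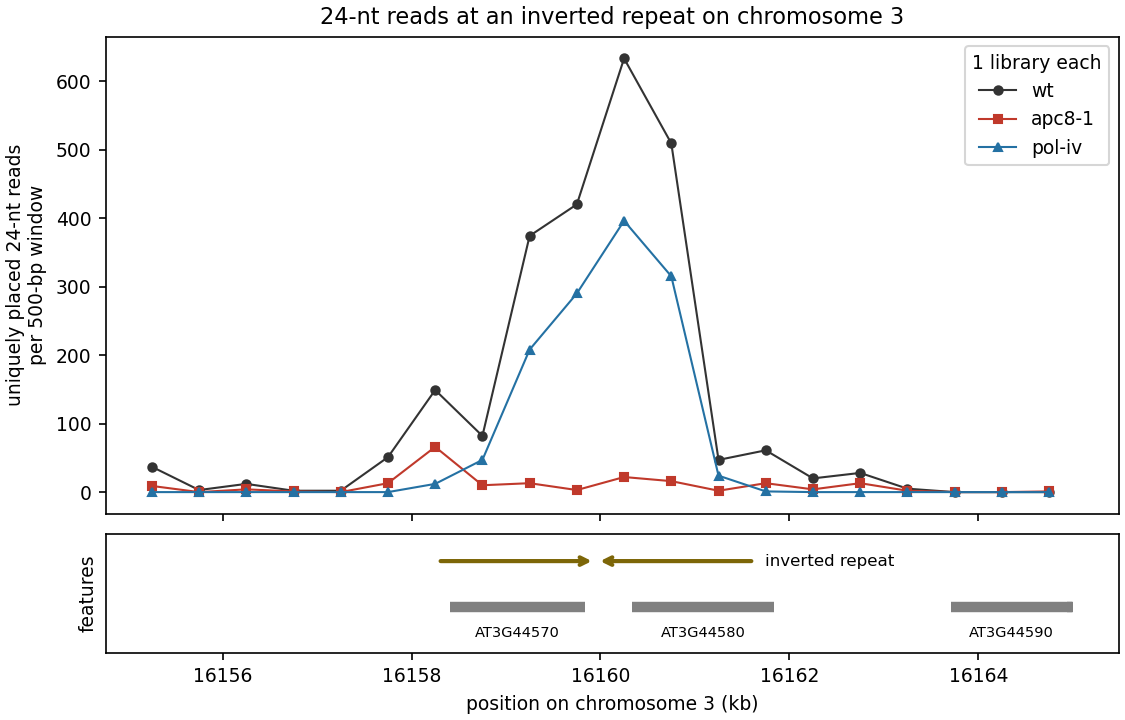
Uniquely placed 24-nt reads per 500-bp window on chromosome 3 (position in kb) in the 3 libraries, above a map of the inverted repeat (arrows) and annotated genes (grey). The window 16160001 to 16160500 has 633 reads in wt, 22 in apc8-1 and 396 in pol-iv.

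Other loci lower in apc8-1 had no pol-iv read, except those said below, and were single windows. The window 903 bp downstream of GSTU5, a glutathione transferase gene, on chromosome 2 (12623001 to 12623500) had 156 reads in wt and 11 in apc8-1, 14.2-fold lower (ratio 0.0705, 0.0345 to 0.130). The non-coding gene AT2G00810 on chromosome 2 (11550001 to 11550500) had 231 and 19 reads. The window 557 bp downstream of LHCA2, a light-harvesting protein gene of photosystem I, on chromosome 3 (22748001 to 22748500) had 188 and 20. A coding exon of AT2G35460 on chromosome 2 (14906501 to 14907000) had 117 and 11, and the window upstream of AT3G27910 on chromosome 3 (10359501 to 10360000) had 133 and 14. Windows upstream of AT2G25800 had 202 and 26 reads, of AT1G55050 117 and 14, and of MLP28 183 and 28, with 1 read of pol-iv at MLP28. The snoRNA cluster of AT5G15022, which was higher in pol-iv, had 1280 reads in wt and 202 in apc8-1 (0.158, 0.135 to 0.183). It was not alone in this, as the other named snRNA or snoRNA windows higher in pol-iv were lower in apc8-1 too. The window of AT3G24615 had 83 and 26 reads, AT1G20015 124 and 31, AT1G05247 121 and 30, and AT4G06010 25 and 4. The whole snRNA or snoRNA class was at 0.850 of wt in apc8-1 (0.818 to 0.884).

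Of the loci higher in apc8-1, the non-coding gene AT3G07775 on chromosome 3 (17520001 to 17520500) had 13 reads in wt and 111 in apc8-1, 8.54 times (4.79 to 16.5), and no pol-iv read. An exon outside the coding sequence of KOR2, an endoglucanase gene, on chromosome 1 (24395501 to 24396000) had 114 and 409 reads, 3.59 times (2.91 to 4.46). A coding exon of HVA22H on chromosome 1 (6926501 to 6927000) had 95 and 214, with 123 in pol-iv. AGL36, an imprinted MADS-box gene on chromosome 5 (9344501 to 9345000), had 39 and 86, and the other 6 loci were between 1.88 and 2.30 times wt. The 20 named loci of this comparison kept their direction when scaled by the listed miRNA, the listed tasiRNA or all 24-nt reads. These scalings shift every locus alike, and loci chosen as the extremes lay too far from 1 to reverse, so this is no separate support.

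Of the RdDM targets, 5 were measured in apc8-1, and all had fewer reads than in wt, with a median log2 ratio of -1.10. Of these, 3 were at least 2-fold lower, and none was when scaled by all 24-nt reads. SDC had 101 reads in wt and 73 in apc8-1 (ratio 0.723, 0.527 to 0.986) and QQS had 37 and 17 (0.459, 0.243 to 0.837). The intervals of FWA with 29 and 18 reads, SNC1 with 16 and 7 and IBM1, a histone demethylase gene, with 15 and 7 included 1. Scaled by the listed miRNA reads, the intervals of these 3 genes lay below 1. This rests on MIR163, as the listed miRNA genes were at 1.23 of wt with it and at 0.753 without it. The interval of SDC included 1 when scaled by all 24-nt reads, and those of SDC, at 1.09, and QQS, at 0.667, did so when each distinct sequence was counted once. The pathway genes DRD1, with 42 and 28 reads, and DCL3, with 40 and 31, also had intervals that included 1, and DCL3 was 1.26 times wt with each distinct sequence counted once. APC8, the mutated gene, had 1 read in each of these libraries, too few to check the label. DMS3, which is not mutated here, had none.

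Of the miRNA families, 10 were measured in apc8-1, with a median log2 ratio of -0.15, 7 below and 2 above wt, and 9 within 2-fold of wt. Scaled by all 24-nt reads, 4 were below and 6 above. MIR156, a family that regulates developmental phase change, was the exception with 113 and 44 reads (0.389, 0.268 to 0.556). It was at 0.60 (0.0932 to 3.08) with each distinct sequence counted once. The gene MIR156d alone had 110 and 42 reads. Mature miRNAs are mostly shorter than 24 nt, so these reads do not measure mature miR156. MIR163 was higher with 1134 and 1597 reads (1.41, 1.30 to 1.52). Of the tasiRNA genes, 5 were measured and all were within 2-fold. TAS1C had 2332 and 2412 reads (1.03, 0.977 to 1.10), TAS2 568 and 668 (1.18, 1.05 to 1.32) and TAS3 197 and 112 (0.569, 0.447 to 0.721). Scaled by the listed miRNA reads, all 5 were below wt, with TAS2 at 0.955 and TAS3 more than 2-fold lower at 0.462 (0.363 to 0.585). MIR163 supplied most of the reads used for this scaling.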

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

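All tests in this part were chosen after the patterns they address were seen, and only the value of the count of every sequence that matches the inverted repeat had not been seen by then. Reads with no exact place in the genome were counted in the totals but in no class, window or list, and their share was above that of wt in both mutants. It was 6.75% (6.72 to 6.79) in apc8-1 and 12.5% (12.3 to 12.7) in pol-iv, against 6.34% in wt.

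Abundant Pol IV-dependent windows had higher apc8-1 to wt ratios than the others. The median log2 ratio of windows with 40 to fewer than 300 reads minus that of windows with 300 or more was -0.26 (bootstrap interval -0.31 to -0.23). A lower depth of the apc8-1 library would give 1 ratio in every window, and redraws at 1 ratio gave differences from -0.02 to 0.02. Position does not account for it, since the difference was -0.25 within arms and -0.35 within pericentromeres, nor do a few abundant sequences, since it was -0.27 without the 3 most abundant sequences of each window. An effect of the apc8-1 genotype that may differ between strong and weak loci, and a different mix of flower stages, remain open and were not tested. With 1 library per genotype, a difference between library preparations cannot be told apart from the genotype either.

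The inverted repeat on chromosome 3 lost most of its 24-nt reads in apc8-1, where pol-iv was at 0.609 of wt, and the 12 windows beside it were lower too, at 0.294 of wt (0.208 to 0.409). Reads moved to sequences with several places cannot account for this, because every sequence that matches the repeat gave a ratio of 0.0423 (0.0346 to 0.0513). The 247 Pol IV-dependent windows within 500 kb had a median ratio of 0.675, which argues against a loss of that size over this wider part of the chromosome. A divergent segment linked to APC8, which lies 1.62 Mb away, would bring sequences of its own. Between 16 and 19 Mb, 13 sequences of apc8-1 alone matched 1 place with 1 mismatch, against 21 of wt alone. Of these, 0 and 5 lay in the repeat itself, and the whole genome held 466 and 532. Sequences with more mismatches or absent from the reference were not searched, so these counts cannot decide on such a segment. A deletion or other change at or around the repeat in this line may exist and was not tested, nor was an effect of the genotype.

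The low 24-nt total of pol-iv was weighed against a shallow library and against a wrong label on a library with the siRNA of wt. The listed miRNA and tasiRNA genes together had 4852 reads in wt and 4556 in pol-iv, a ratio of 0.939 (0.902 to 0.978), far above the 0.0375 of the total, and without MIR163 and TAS1C the ratio was 0.971. Of 10309 windows with at least 20 wt reads, 91.3% held no pol-iv read, against 19.2% for wt thinned to the pol-iv total. The loss is consistent with the stated genotype, and a mutant of another step that makes 24-nt siRNA, under a wrong label, was not tested and remains open.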

How the results depend on the processing

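The tests that scaled by tasiRNA or by all 24-nt reads, shared out places, counted distinct sequences in windows, chose windows on the sum or left out the 100 strongest windows, MIR163, TAS1C or the inverted repeat were chosen after the data were seen. Values below stand in the order in which they are named, and the cause was not tested where a value moved. In apc8-1, the total was 0.681 of wt when scaled by miRNA reads, 0.818 by tasiRNA reads, 0.829 with each distinct sequence counted once, and reversed to 1.11 when scaled by miRNA reads without MIR163. The sum of the listed miRNA genes itself reversed to 0.753 without MIR163. The other apc8-1 values scaled by miRNA reads therefore rest largely on this gene. Intergenic reads were at 0.701 scaled by miRNA reads, 0.842 by tasiRNA reads and 0.811 with distinct sequences. Scaled by all 24-nt reads, intergenic reads reversed to 1.03 and protein-coding genes to 1.02 of wt, and the median log2 ratio of the miRNA and tasiRNA list moved to 0.13. TAS2 reversed to 0.955 of wt when scaled by miRNA reads, and SDC to 1.09 with distinct sequences. In pol-iv, the total was 0.0255 scaled by miRNA reads, 0.0189 by these without MIR163, 0.0545 by tasiRNA reads, 0.0218 without structural RNA and organelles, and 0.0241 with distinct sequences. Intergenic reads were at 0.00245 scaled by miRNA reads, 0.00523 by tasiRNA reads and 0.00570 with distinct sequences. Scaled by tasiRNA reads, the median log2 ratio in pol-iv was 1.46 for the miRNA and tasiRNA list and -3.20 for RdDM genes and targets, the latter -3.00 with distinct sequences. MIR163 reversed to 0.869 of wt when scaled by miRNA reads and TAS1C to 1.10 by tasiRNA reads, where each supplied most of the reads that scaled it. With distinct sequences, MIR168 reversed to 0.80 and MIR319 to 0.857. The share of Pol IV-dependent windows lower in apc8-1 was 12.9% with at least 50 reads, 5.73% scaled by the median window ratio, 37.5% by miRNA reads, 11.3% by all 24-nt reads, 46.3% at 1.5-fold and 8.59% with distinct sequences. The share higher was 0.274% in 1000-bp windows, 3.38% scaled by the median window ratio, 0.142% by miRNA reads, 0.184% by tasiRNA reads, 1.25% by all 24-nt reads, 2.42% at 1.5-fold, 0.0956% with Pol IV dependence at 10-fold, 0.220% with places shared out and 0.212% with distinct sequences. The median log2 ratio was -0.58 with at least 10 reads, -0.47 with at least 50, -0.49 in 200-bp and -0.55 in 1000-bp windows, 0.00 by construction scaled by the median window ratio, -0.82 by miRNA reads, -0.57 by tasiRNA reads, -0.27 by all 24-nt reads, -0.30 with distinct sequences and -0.47 with windows chosen on the sum. In pol-iv, 83.4% of windows or more were called lower over the settings tried. The lowest share came with a minimum of 10 reads. There, the floor of 3 pol-iv counts bars windows with few wt reads from the call even without a pol-iv read. None of the 37 named loci with other settings reversed in 94 values. Only scalings of whole libraries were run on them, and their choice as extremes left no room for a reversal. Scaling by 21-nt reads and all lengths were not run, because the files hold 24-nt reads alone. A larger pseudocount was meant for normalized values and was not run on these counts, and the median window ratio could not scale pol-iv, as it was 0. Leaving out structural RNA and organelle reads left the intergenic class and the medians of the lists unchanged. In apc8-1, 7 of 20 RdDM genes and targets and 10 of 31 miRNA families had enough reads to be measured.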

Other observations

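The genes and reads described here were chosen after their values were seen. Many annotated miRNA genes outside the listed families gave 24-nt reads that depended on Pol IV. Of 63 annotated miRNA genes with at least 20 wt reads, 44 were at least 4-fold lower in pol-iv, and none of these belonged to a listed family, whose 8 such genes were all retained. MIR5645a on chromosome 3 (17418776 to 17419220) had 788 reads in wt, 534 in apc8-1 and 0 in pol-iv, and MIR5653 on chromosome 1 (19026915 to 19027000) had 672, 527 and 0. MIR5635a on chromosome 5 (6926005 to 6926446) had 462, 303 and 3. MIR5642a on chromosome 3 (14196774 to 14197147), in contrast, kept 219 of 464 reads in pol-iv, and MIR4245 on chromosome 5 (21161506 to 21161652) had 163 in wt, 131 in apc8-1 and 336 in pol-iv. In apc8-1, 39 of the 44 Pol IV-dependent genes were below wt, with a median ratio of 0.676. Several of these genes share sequences, so they are not independent.

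Sequences with no exact place included reads that begin with the first 18 nt of an annotated mature miRNA and end in other bases. Those of MIR158 with a tail of T alone had 1336 reads in wt, 1325 in apc8-1 and 817 in pol-iv, and with another tail 1238, 1394 and 815. Over all families, the T-tailed reads were 1446, 1416 and 944. The first base of the 24-nt reads was A in 60.1% of wt reads, 59.9% of apc8-1 reads and 32.8% of pol-iv reads. Among intergenic reads, the share of A was 61.8%, 61.5% and 44.2%.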
